A study of Mus musculus with 6 samples.

How the data were processed

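Single-cell RNA was measured in the mouse submandibular salivary gland with droplet libraries of the 10x Genomics 3' v3 chemistry. Per the labels, 3 libraries were made: a basal epithelial sort of untreated glands, the whole epithelium of untreated glands, and the whole epithelium of glands 90 days after 30 Gy to the left gland. Each library pooled 3 female C57BL/6J mice, carrying 3 hashtag antibodies that mark replicates 1, 2 and 3. The labels give an age of 8 to 10 weeks for all mice. For the irradiated mice this cannot be the age at collection, which was 90 days after the dose. Per the labels' protocols, dissociated cells were sorted as Epcam-positive (whole epithelium) or as Epcam-positive and Cd49f-high (basal sort), without DAPI-positive cells and without cells positive for Cd3, Cd16/32, Cd31 or Cd45. The labels do not say when each library was prepared.

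The deposited values are raw UMI counts per gene or hashtag antibody and cell barcode, which the authors made with Cell Ranger 6.1.2 on the mm10 build, per the submitters' processing notes. The deposited files hold filtered barcodes (5044 in the basal sort, 8277 in the untreated and 3319 in the irradiated epithelium) and 32285 genes. Gene UMIs summed to 59207148, 137835128 and 58485558, and the median per barcode was 11985, 6755 and 16995. The median mitochondrial share over all barcodes was 5.19%, 19.3% and 5.25%.

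Cells needed at least 500 genes and at most 20% mitochondrial UMIs, which left 4418, 4093 and 2629. Hashtags were called with HTODemux of Seurat 5.3.0 (R 4.3.3) at a positive quantile of 0.99. With the tool's default of 4 starting clusters 1267 irradiated barcodes had no call. With 5 starting clusters 294 had none, and the barcodes that so gained a hashtag 2 call held a median of 218 hashtag 2 UMIs, against 27 in cells of the other mice. These medians were 118 and 46 in the basal sort, and 158 and 69 in the untreated epithelium. The 5 starting clusters were therefore used, a choice made after seeing the hashtag counts. Hashtag doublets (231, 158 and 182) and barcodes without a hashtag call (967 or 21.9%, 1719 or 42.0%, and 294 or 11.2%) were left out. Of the singlets to which a rule of at least 70% of hashtag UMIs and at least 10 UMIs also gave a mouse, it gave the same mouse to 100%, 100% and 99.0%. The rule gave a mouse to 2242 of 3220, 810 of 2216 and 1992 of 2153 singlets, so this agreement does not cover the others. Doublets within a mouse were removed by Scrublet score (scanpy 1.11.5), as many as the hashtag doublets predict (116, 79 and 91). The score separated hashtag doublets from singlets with an area under the curve of 0.591, 0.611 and 0.583, so many such doublets stay in. The cells kept were 3104, 2137 and 2062.

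Kept cells of the 3 libraries were clustered together with no batch correction (scaling to 10000 counts, log, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1). A cluster was named "X-like" after the marker list, of 15 fixed before the data were examined, whose markers were raised most (at least 1.5-fold, in at least 10% of cells, at least 3 markers). A cluster in which at least 90% of the markers of each of 2 specific lists were raised was called mixed. A cluster whose leading genes went against its name, or whose UMI median was low (under 1 in 3 of its library) with no marker of that name among its top 10 genes by fold over all other clusters, stayed unnamed. The former was judged by the top 10 genes by fold over clusters of other classes. These names were rebuilt here from the counts.

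The replicate is the mouse (n = 3 per group), and a group is 1 library, so both coincide, as does age after irradiation. Counts were summed per mouse over all kept cells, and over granular duct-like and ionocyte-like cells. A class was tested where every mouse held at least 20 cells. Sums were tested with edgeR 4.0.16 (limma 3.58.1): filterByExpr, TMM, quasi-likelihood F test, Benjamini-Hochberg over all tested genes, threshold 0.05. The basal sort and the irradiated epithelium were each compared with the untreated whole epithelium, so these comparisons share their controls. Whether the irradiation effect differed between the classes was tested as an interaction with a block per mouse. Numbers of cells per class and mouse were tested with the same edgeR test with the number of kept cells as offset, for classes of at least 10 cells, beside an exact permutation test of the shares, which with 3 mice against 3 gives no p under 0.1. Amounts are CPM, mean ± SD over mice, and log2 fold changes carry their standard error.

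The gene lists (26) and the named genes follow rules fixed before the data were examined. Named are the 8 genes per direction (all cells) or 5 (within a class) with the largest change among those past the threshold, without overlap between mice and with a mean of at least 10 CPM over the 6 mice (no Gm, Rik, mitochondrial or ribosomal protein names), and up to 4 genes per described list with the smallest p. Some genes that the rule names are not reported here. The lists were written from general knowledge of these pathways, and some share genes. Lists with at least 5 tested genes were tested with camera at a correlation of 0.01, and again with the estimated correlation and with fry. A gene with 0 counts in a group is given as "at least" a fold, from a floor of 3 counts over the group. With 1 to 3 counts the ratio and its 95% counting interval are given.

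Free RNA was assumed to keep the ratios between the genes of its library, which was not measured, since the files hold filtered barcodes. In each class and group it was bounded by the products of other cell types, from the lowest median ratio of the level in the class to the level in the library. A gene of which free RNA could give at least 50% of the level in the higher group is named as such in the text. In the irradiation comparison this held for 9 changed genes of granular duct-like and 10 of ionocyte-like cells. The reference table gives coordinates on the mm10 build by symbol, and 26259 symbols matched once.

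Each fit was tested on simulated data with the observed sums per mouse and spread, in which 100 genes were changed 2-fold and 100 genes 4-fold. Of 12407 genes in the basal comparison, 99 of the 2-fold and 99 of the 4-fold genes were found, with 18 false calls. For all irradiated cells (11726 genes) it was 97 and 100 with 13 false calls, for granular duct-like cells (9683 genes) 98 and 100 with 9, for ionocyte-like cells (8714 genes) 90 and 100 with 17, and for the interaction (9966 genes) 77 and 100 with 19. DESeq2 1.42.0 found 100 and 99, 98 and 100, 97 and 100, and 81 and 98 in the first 4 fits (12407, 11044, 9683 and 8714 genes tested), with 29, 15, 7 and 8 false calls. A list raised 2-fold was called in all 4 fits, as was 1 unraised list each in the basal and the all-cell irradiated fit and 0 in the other fits. The simulated gene changes were few and evenly split between higher and lower. The real fits called more genes, up to 9469 of 12933, so normalization and false calls in that setting were not tested.

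Alternatives planned before the data were examined were DESeq2, upper-quartile factors, no filter on low counts, thinned sums, dominant genes left out, a replicate block, each mouse left out, the hashtag share rule, hashtag doublets alone removed, a filter of 1000 genes and 10% mitochondrial UMIs, resolutions 0.5 and 2, each library clustered alone, TMM factors over classes, and other list tests. The default hashtag start, barcodes without a hashtag call kept, genes explained by free RNA left out, acinar-like cells left out, the low-UMI cluster named by its markers, and most alternatives of the interaction were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9, and Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Not analysed were velocity or trajectories, splicing and sequence variants, since the files hold no reads.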

Results

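RNA was counted in single cells of the mouse submandibular gland, a major salivary gland whose acini make the saliva proteins and whose ducts modify the fluid and secrete growth factors and kallikreins. There were 3 groups of female C57BL/6J mice, a common inbred laboratory strain. The first group was a basal sort of untreated glands, that is, cells positive for the epithelial surface protein Epcam and high in Cd49f (integrin alpha 6, gene Itga6), which anchors basal cells to the basement membrane. The second was the whole Epcam-positive epithelium of untreated glands, and the third the whole Epcam-positive epithelium of glands collected 90 days after a dose of 30 Gy to the gland. Sorting set aside dead cells and cells carrying Cd3, Cd16 or Cd32, Cd31 or Cd45, so all shares given here are shares of sorted, dissociated cells. Each group was 1 library that pooled 3 mice, which were told apart by antibody hashtags (n = 3 mice per group throughout). Library and group can therefore not be told apart, nor age in the irradiation comparison.

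After the filters, 3104 cells of the basal sort, 2137 of the untreated epithelium and 2062 of the irradiated epithelium were kept. Total counts per mouse ran from 9325900 to 18719496 UMIs in the basal sort, from 12633448 to 14233078 in the untreated epithelium and from 7138692 to 27757496 in the irradiated epithelium. The median mitochondrial share per mouse, a sign of RNA quality, was 4.88% ± 0.349 of UMIs in the basal sort, 9.51% ± 0.508 in the untreated epithelium and 4.36% ± 0.377 in the irradiated epithelium (mean ± SD, n = 3 mice each). Among the sort genes, Epcam stood at 1321 ± 124, 1193 ± 59.8 and 2071 ± 124 CPM, the counts scaled to a common total per mouse, in the basal sort, the untreated epithelium and the irradiated epithelium. In the same order Itga6 stood at 157 ± 16.0, 81.0 ± 6.98 and 110.0 ± 3.44 CPM, and Kit, a receptor of intercalated duct cells, at 5.51 ± 5.86, 41.9 ± 6.14 and 22.9 ± 4.76 CPM. Pecam1, the gene of the gated endothelial protein Cd31, stood at 13.9 ± 4.38, 3.85 ± 1.47 and 1.82 ± 1.05 CPM. The leukocyte gene Ptprc (Cd45) had 0 counts in the basal sort, which allows up to 0.0599 CPM, and a mean of 0.347 CPM in the untreated and 0.101 CPM in the irradiated epithelium. Fcgr3, Fcgr2b and Cd3e, the other gated immune genes, had between 0 and 18 counts in each group.

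Clustering of all kept cells gave 21 clusters. Clusters 0 to 4 carried basal duct markers such as Krt5, Krt14 and Krt17, and of these cluster 4 was led by the interferon-inducible gene Ifi202b and the wound keratin Krt6a. Cluster 5 was myoepithelial-like (Acta2, Tagln, Myh11), cluster 6 endothelial-like (Flt1, Plvap, Kdr) and cluster 7 cycling (Ube2c, Top2a, Cdk1). Clusters 8 and 12 were intercalated duct-like (Kit, Gfra3, Elf5), and the inflammatory genes Cxcl2, Cxcl1 and Lcn2 were among the leading genes of cluster 12. Cluster 9 was luminal duct-like and was led by the oxidase genes Duoxa2 and Duox2 together with the stress-responsive genes Areg and Gdf15. Cluster 14 was acinar-like (Bhlha15, Aqp5, Pip), with a median of 80642 UMIs per cell, and cluster 18 was fibroblast-like with 13 cells. Granular duct-like cells, which carried Egf and many tissue kallikreins (Klk1b genes), lay in cluster 11 in the untreated epithelium and in clusters 19 and 20 in the irradiated epithelium. Ionocyte-like cells, which carried Ascl3, Foxi1 and proton pump genes, lay in cluster 13 in the untreated and in cluster 15 in the irradiated epithelium. Cluster 16 held markers of both ionocytes and granular ducts, and clusters 10 and 17 stayed unnamed. Cluster 10 (39 untreated and 99 irradiated cells) had all 9 ionocyte markers raised, but a median of 2283.5 UMIs and none of these markers among its top 10 genes by fold over all other clusters. No cluster of the kept cells was named after tuft, immune, neural, erythroid or striated duct markers.

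The first comparison asked what the Cd49f-high sort holds beside the whole untreated epithelium. Basal duct-like cells made up 82.8% ± 1.05 of the cells of a mouse in the basal sort and 2.57% ± 0.627 in the whole epithelium (log2 ratio of shares 5.00 ± 0.34 SE, adjusted p = 2.7e-07, edgeR). Contractile myoepithelial-like cells rose from 0.181% ± 0.313 to 6.47% ± 2.88 (adjusted p = 2.4e-04), cycling cells from 0.376% ± 0.168 to 2.22% ± 1.06 and endothelial-like cells from 0.878% ± 0.532 to 3.59% ± 1.24 (both adjusted p = 0.0043). In the opposite direction, granular duct-like cells made up 29.5% ± 1.52 of the whole epithelium and 0.0913% ± 0.0991 of the basal sort, and ionocyte-like cells 24.6% ± 3.75 and 0.0420% ± 0.0727 (both adjusted p = 2.7e-07). Intercalated duct-like cells fell from 25.1% ± 4.88 to 4.31% ± 4.23 (adjusted p = 0.0024) and luminal duct-like cells from 1.73% ± 0.389 to 0.396% ± 0.145 (adjusted p = 0.0077). Acinar-like cells made up 5.53% ± 0.794 of the whole epithelium, and 0 of 3104 cells in the basal sort, which allows a share of up to 0.0966% (adjusted p = 1.3e-05). Of the cells without a single class name, the mixed cluster fell from 2.97% ± 1.09 to 0 (adjusted p = 1.9e-04) and the unnamed clusters from 6.02% ± 0.972 to 0.117% ± 0.104 (adjusted p = 1.1e-05). The share of fibroblast-like cells did not pass the test (adjusted p = 0.053). The exact two-sided permutation test of each of the 11 changed shares gave p = 0.1, the smallest value that 3 mice against 3 allow. With TMM factors over the classes in place of the number of cells, the intercalated duct-like ratio was -0.31 and the luminal duct-like ratio 0.031, both no longer past the threshold. The endothelial-like ratio of 2.01 no longer passed without untreated mouse 1 (1.78, adjusted p = 0.073), with the replicate number as a block (2.06, 0.076), with mice assigned by hashtag share (1.06, 0.16) or with the stricter cell filter (0.94, 0.15), and was 2.63 without untreated mouse 2. The cycling ratio of 2.55 did not pass with mice assigned by hashtag share (1.67, 0.23), the luminal duct-like ratio of -2.04 not without untreated mouse 1 (-1.99, 0.052) and the unnamed ratio of -5.41 not with each library clustered alone (-0.48, 0.33). The fibroblast-like ratio of -5.43 passed without untreated mouse 1 (-6.05, 0.011), with the block (-5.00, 2.7e-05), with the share rule (-5.68, 0.0080) and with each library clustered alone (-5.43, 0.039). Leaving out a mouse moved the ratios of myoepithelial-like cells from 5.03 to 8.88 (untreated mouse 2), of intercalated duct-like cells from -2.57 to -3.74 (basal-sort mouse 2), of granular duct-like cells from -8.06 to -8.89 (basal-sort mouse 3) and of ionocyte-like cells from -9.03 to -8.43 and -10.78 (basal-sort mice 1 and 2).

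**Figure D1:**
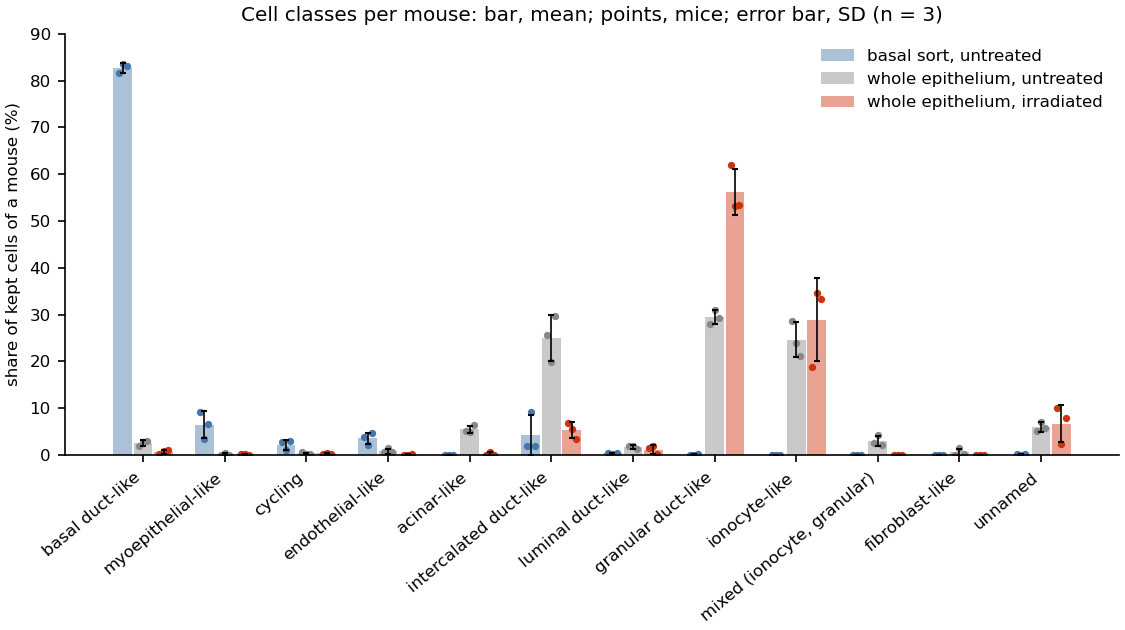
Share of the kept cells of each mouse (%) in each cell class for the basal sort, the untreated whole epithelium and the irradiated whole epithelium; bars are means, points are mice and error bars are SD (n = 3 mice). Basal duct-like cells stood at 82.8% in the basal sort, and granular duct-like cells at 29.5% in the untreated and 56.3% in the irradiated epithelium.

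Over all kept cells, the basal sort was higher in genes of basal adhesion, contraction, Notch and Wnt signalling and cell division, and lower in secreted products of acinar and granular duct cells. As lists these groups passed camera, and none of them passed with an estimated correlation. Krt5, the basal keratin, stood at 462 ± 44.1 CPM in the basal sort and 11.5 ± 4.24 CPM in the whole epithelium (log2 fold change 5.33 ± 0.26 SE, adjusted p = 2.7e-07, edgeR, here and in what follows). Scgb1b27, a secretoglobin of acinar cells, stood at 23.2 ± 2.46 and 46464 ± 5592 CPM (log2 -10.97 ± 0.15, adjusted p = 4.0e-10). Of 12933 genes tested, 4683 rose and 4786 fell. In the reference table, which uses the same mouse genome build as the counts (mm10, GRCm38), Krt5 lies on chromosome 15 from 101707069 to 101712905, and Scgb1b27 on chromosome 7 from 34021481 to 34022881.

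The largest increases that met the naming rule were those of Fam180a (log2 5.87 ± 0.27), Tenm2, a synaptic adhesion protein (5.85 ± 0.38), the axon guidance receptor Robo2 (5.67 ± 0.18) and Snai2, a transcription factor of epithelial plasticity (5.63 ± 0.27). Pdpn, a mucin-type membrane glycoprotein (5.61 ± 0.22), Clca3a2 (5.52 ± 0.30), the gap junction gene Gja1 (5.40 ± 0.28) and the fibril-associated collagen Col12a1 (5.40 ± 0.17) followed, with adjusted p between 4.9e-08 and 1.3e-06 for these 8 genes. The largest decreases were those of Dcpp3, Dcpp2 and Dcpp1, related secreted proteins with 0 counts in the basal sort, which were at least 51603-fold, 33618-fold and 15074-fold lower (floor of 3 counts over the group). The Dcpp levels of the whole epithelium came almost entirely from mouse 3, with 9615 CPM of Dcpp3 against 3.79 and 4.22 CPM in the other mice, and without it the limits were 68.2, 33.4 and 52.3. Without untreated mouse 2 they were 79871, 52038 and 23319, and without basal-sort mouse 1 28610, 18639 and 8357. Smgc, a mucin of the immature gland, fell by 13.81 ± 0.74 on the log2 scale, and Car6, the secreted carbonic anhydrase, by 11.59 ± 0.24. Without basal-sort mouse 2 Smgc was at -15.16, and without untreated mouse 2 Clca3a2 was at 6.15. Scgb2b26 (-11.32 ± 0.14) and Wfdc12 (-11.25 ± 0.26) fell as well. Mup5, with 3 counts or fewer in the basal sort, was lower by a ratio of 3078 (95% counting interval 1053 to 14928), or of 5119 without basal-sort mouse 1. Counts of close copies such as the Dcpp, Klk1b and H2-Q genes are uncertain, since reads can be split between copies.

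All 20 basal keratin and adhesion genes rose (20 adjusted over the list alone; camera adjusted p = 6.1e-15, adjusted p = 0.18 with an estimated correlation). Col17a1, the hemidesmosome collagen (5.23 ± 0.20), the cytolinker Dst (3.25 ± 0.09) and the adhesion gene Cdh3 (4.84 ± 0.25) rose. All 13 contractile genes tested rose (13 adjusted over the list alone; camera adjusted p = 0.0028, adjusted p = 0.51 with an estimated correlation). The myosin kinase Mylk (4.58 ± 0.41), the tropomyosins Tpm2 (4.55 ± 0.56) and Tpm1 (2.17 ± 0.13), and Smtn (2.19 ± 0.16) rose. Without untreated mouse 2 Mylk was at 5.58 and Tpm2 at 5.59. Of 24 proliferation genes 23 rose and 1 did not pass (23 adjusted over the list alone; camera adjusted p = 3.9e-04, adjusted p = 0.53 with an estimated correlation). The replication helicase genes Mcm6 (1.94 ± 0.14) and Mcm4 (1.19 ± 0.11), the tubulin regulator Stmn1 (2.58 ± 0.19) and Hmgb2 (1.42 ± 0.11) rose. All 6 class II antigen presentation genes tested rose (6 adjusted over the list alone; camera adjusted p = 1.2e-04, adjusted p = 0.18 with an estimated correlation). Among them Cd74, the invariant chain, stood at 169.6 ± 10.4 and 10.2 ± 1.12 CPM, while the leukocyte gene Ptprc had 0 counts in the basal sort. Of 12 Notch genes 9 rose and 2 fell (11 adjusted over the list alone; camera adjusted p = 0.0019, adjusted p = 0.28 with an estimated correlation). The ligands Dll1 (4.56 ± 0.32) and Jag2 (4.10 ± 0.29), the receptor Notch1 (2.80 ± 0.14) and the target Hes1 (2.59 ± 0.17) rose, with Jag2 at 4.73 without untreated mouse 3. Of 18 Wnt genes 13 rose and 2 fell (15 adjusted over the list alone; camera adjusted p = 0.0015, adjusted p = 0.37 with an estimated correlation). The ligand Wnt10a (4.44 ± 0.19), the transcription factor Lef1 (4.22 ± 0.27) and the secreted inhibitor Notum (2.59 ± 0.23) rose, and the ligand Wnt4 (-2.51 ± 0.16) fell.

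All 14 acinar secretory products tested fell (14 adjusted over the list alone; camera adjusted p = 1.2e-15, adjusted p = 0.18 with an estimated correlation). Scgb2b27 (-10.90 ± 0.20) and Oit1 (-6.99 ± 0.21) fell. Of 20 granular duct products 18 fell and 2 rose (20 adjusted over the list alone; camera adjusted p = 1.9e-16, adjusted p = 0.21 with an estimated correlation). The kallikreins Klk1b4 (-10.09 ± 0.28), Klk1b21 (-10.01 ± 0.39) and Klk1b27 (-6.37 ± 0.23) and the secreted protein Crisp3 (-8.60 ± 0.30) fell. Of 18 duct ion transport genes 15 fell and 2 rose (18 adjusted over the list alone; camera adjusted p = 2.3e-08, adjusted p = 0.19 with an estimated correlation). The proton pump subunit Atp6v0d2 (-6.26 ± 0.15), the sodium channel subunit Scnn1b (-5.33 ± 0.13) and the sodium pump regulator Fxyd2 (-4.11 ± 0.11) fell. All 23 oxidative phosphorylation genes fell (23 adjusted over the list alone; camera adjusted p = 8.8e-08, adjusted p = 0.37 with an estimated correlation). Cox5a (-1.80 ± 0.09), Ndufa1 (-1.74 ± 0.08), Sdhb (-1.67 ± 0.09) and Cyc1 (-1.63 ± 0.09) fell, beside the mitochondrial shares of 4.88% and 9.51% given for these cells.

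The other lists of this comparison are given by their counts. Acinar regulators and fluid secretion genes fell in 23 of 25 cases, luminal keratins and junctions in 10 of 16 and unfolded protein genes in 14 of 22, and squamous differentiation genes rose in 6 of 9, matrix genes in 11 of 15, senescence-associated secretory genes in 12 of 17 and NF-kB genes in 11 of 18. All 7 of these lists passed camera, with adjusted p between 4.2e-13 and 0.049, and none passed with an estimated correlation (adjusted p between 0.18 and 0.51). Neither p53 targets (11 of 24 rose, 7 fell), interferon genes (6 of 29 rose, 19 fell), class I genes (7 of 16 rose, 6 fell) nor immediate-early genes (3 of 18 rose, 11 fell) passed camera as lists. Heat shock genes (8 of 13 rose, 1 fell) and DNA repair genes (5 of 22 rose, 5 fell) did not pass either, nor did oxidative stress genes (6 of 21 rose, 9 fell), progenitor-associated genes (7 of 18 rose, 8 fell) or retinoic acid genes (6 of 12 rose, 2 fell). For the oxidative stress and the progenitor-associated genes the median change and the camera test differed in sign. The within-class comparison planned for basal duct-like and myoepithelial-like cells was not run, since a mouse of the whole epithelium held fewer than 20 cells of each class.

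**Figure D2:**
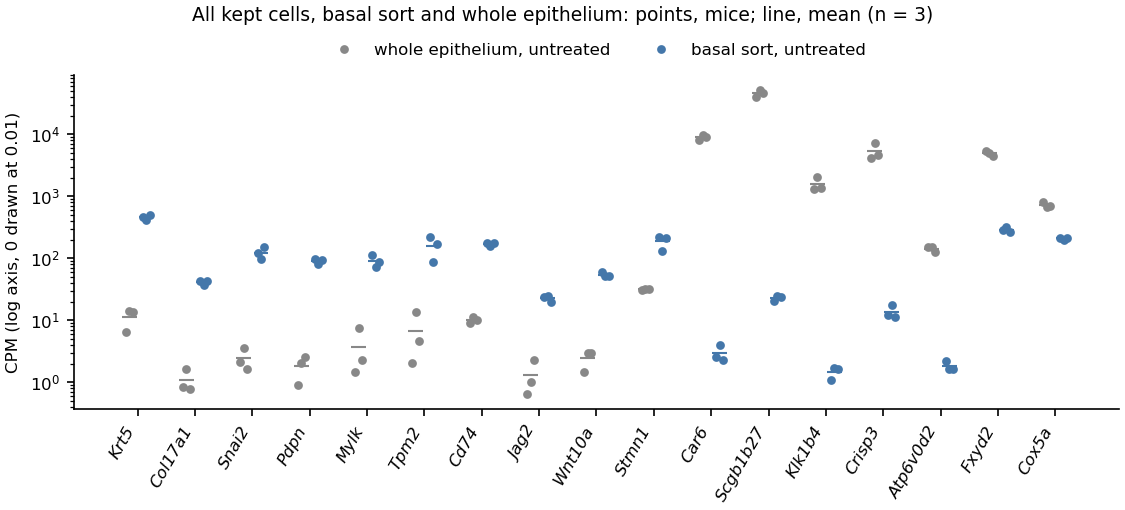
CPM (log axis, values of 0 drawn at 0.01) of 17 named genes over all kept cells of each mouse in the basal sort and the untreated whole epithelium; points are mice and lines are means (n = 3 mice). Krt5 stood at 462 CPM in the basal sort and 11.5 CPM in the whole epithelium, and Scgb1b27 at 23.2 and 46464 CPM.

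The second comparison asked how the whole epithelium differed 90 days after irradiation. Granular duct-like cells made up 56.3% ± 4.94 of the cells of an irradiated mouse and 29.5% ± 1.52 of those of an untreated mouse (log2 ratio of shares 0.93 ± 0.14 SE, adjusted p = 1.4e-04, edgeR). Acinar-like cells fell from 5.53% ± 0.794 to 0.212% ± 0.367 (-3.94 ± 0.78, adjusted p = 8.4e-04) and intercalated duct-like cells from 25.1% ± 4.88 to 5.33% ± 1.72 (-2.24 ± 0.29, adjusted p = 7.4e-05). The mixed cluster fell from 2.97% ± 1.09 to 0 of 2062 cells, which allows up to 0.145% (adjusted p = 8.4e-04), endothelial-like cells from 0.878% ± 0.532 to 0.0728% ± 0.126 (adjusted p = 0.026) and basal duct-like cells from 2.57% ± 0.627 to 0.725% ± 0.406 (adjusted p = 0.049). These calls did not all hold. The granular duct-like ratio no longer passed with mice assigned by hashtag share (0.52, adjusted p = 0.21). The endothelial-like ratio of -3.71 did not pass without untreated mouse 3 (-3.91, 0.092) or irradiated mice 1 or 2 (-3.51 and -2.65, 0.066 and 0.14), and was -5.75 without irradiated mouse 3. The basal duct-like ratio of -1.73 did not pass with any untreated mouse left out (-1.93, -1.65 and -1.62; 0.17, 0.092 and 0.28), without irradiated mice 1 or 2 (-1.49 and -1.77; 0.11 and 0.061), with TMM factors (-1.30, 0.15), with the replicate number as a block (-1.84, 0.14) or with the share rule (-1.89, 0.093). All 8 irradiated acinar-like cells came from mouse 2, and without it the acinar-like ratio was -8.03. Ionocyte-like cells made up 24.6% ± 3.75 and 28.9% ± 8.86 (log2 0.25 ± 0.24, adjusted p = 0.44), and the shares of cycling and fibroblast-like cells did not pass either (adjusted p = 0.89 and 0.052). The ionocyte-like share passed as higher with cluster 10 counted as ionocyte-like (log2 0.44, adjusted p = 0.020), with TMM factors over the classes (0.73, 0.040), with each library clustered alone (0.45, 0.014), with the stricter cell filter (1.46, 7.6e-05) and without irradiated mouse 1 (0.47, 0.016). The fibroblast-like share (log2 -5.12) passed as lower in 6 settings, namely with TMM factors (adjusted p = 0.040), the replicate number as a block (0.0020), without untreated mouse 1 (0.0075), with mice assigned by hashtag share (0.0067), the stricter cell filter (0.037) and cluster 10 counted as ionocyte-like (0.031). The luminal duct-like ratio of -0.42 did not pass (adjusted p = 0.70) and depended on the processing. It passed as higher with mice assigned by hashtag share (2.62, adjusted p = 7.6e-05), at resolution 2 (3.24, 5.5e-04) and with each library clustered alone (2.73, 8.2e-06), and as lower with the stricter cell filter (-2.03, 1.3e-06). The unnamed share did not pass (log2 0.09, adjusted p = 0.89), and passed as lower with each library clustered alone (-2.18, adjusted p = 0.0030) and with cluster 10 counted as ionocyte-like (-6.00, 1.7e-06). Myoepithelial-like cells, 4 in each group, were too few to test. The exact two-sided permutation p was 0.1 for the 6 changed shares, the smallest possible.

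The intercalated duct-like and the acinar-like shares depended on the clustering and on the choice of cells. The intercalated duct-like log2 ratio was -6.27 with mice assigned by hashtag share and -6.73 with the stricter cell filter (adjusted p = 6.5e-12 and 1.5e-13). Of the irradiated intercalated duct-like cells 101 lay in cluster 12 and 9 in cluster 8. At resolutions 0.5 and 2 a cluster of 102 cells led by Bpifa2, Cxcl2 and Lcn2 stood apart unnamed, and the intercalated duct-like log2 ratio was -5.35 and -5.65 (adjusted p = 7.8e-09 and 4.9e-05). With each library clustered alone, 5.53% of irradiated cells and 5.71% of untreated cells were named acinar-like (log2 ratio -0.20, adjusted p = 0.66), and no irradiated cell intercalated duct-like. Of the 114 irradiated cells so named acinar-like, 83 lay in cluster 12 and 8 in the acinar-like cluster 14 of the joint clustering. Barcodes were called rich in acinar RNA with over 30% of their UMIs from the listed acinar secretory products and Mucl2. Mucl2, a mucin-like saliva protein outside that list, stood at 339932 CPM over all untreated barcodes. Such barcodes made up 18.0% of all 8277 untreated barcodes (95% exact binomial interval 17.2% to 18.8%) and 0.572% of all 3319 irradiated barcodes (0.345% to 0.893%). In the untreated library 48.5% of the barcodes without a hashtag call were rich in acinar RNA, and 7.99% of those with 1 hashtag.

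Over all cells, irradiated mice were lower in acinar products and regulators and higher in p53 targets, interferon response genes, class I antigen presentation genes and inflammatory genes. As lists these groups passed camera, and none of them passed with an estimated correlation (adjusted p between 0.067 and 0.25). Mucl2, a mucin-like saliva protein, fell by 7.02 ± 1.05 on the log2 scale, from 227724 ± 18431 to 1749 ± 1983 CPM (adjusted p = 0.001). B2m, the light chain of class I molecules, rose from 394 ± 29.6 to 1607 ± 59.1 CPM (log2 2.03 ± 0.09, adjusted p = 8.0e-06), and Bax, a pro-apoptotic p53 target, from 46.7 ± 1.92 to 159 ± 15.6 CPM (1.77 ± 0.09, adjusted p = 9.9e-06). Of 11970 genes tested, 2486 rose and 2390 fell. With upper-quartile factors, which shifted the median of all genes by -0.108 on the log2 scale, 37.2% of the changed genes were higher in place of 51.0%. With mice assigned by a hashtag share of at least 70%, 3208 genes changed. On the mm10 build Mucl2 lies on chromosome 15 from 103895855 to 103899312, B2m on chromosome 2 from 122147687 to 122153082, and Bax on chromosome 7 from 45461695 to 45466903.

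Among the largest increases, the antimicrobial lectin gene Reg3g, with 0 counts in untreated mice, was at least 439-fold higher (adjusted p = 1.5e-05), or 284-fold without untreated mouse 2. With a single count each in untreated mice, the calcitonin gene-related peptide gene Calcb was higher by a ratio of 1802 (95% counting interval 323 to 71187) and the milk protein gene Csn3 by a ratio of 1142 (205 to 45147). The ratio of Csn3 came mostly from irradiated mouse 1, with 161 CPM against 3.43 and 21.0 CPM in the other irradiated mice, a spread that the interval does not cover. It was 287 without irradiated mouse 1, 2783 without irradiated mouse 2, 739 without untreated mouse 2 and at least 261 without untreated mouse 3. That of Calcb was 1165 without untreated mouse 2 and at least 411 without untreated mouse 3. Sult1c1, a sulfotransferase, rose by 6.81 ± 0.37, Tnip3, an inhibitor of NF-kB signalling, by 4.66 ± 0.14, the long non-coding RNA Morrbid by 4.58 ± 0.25, the growth factor Areg by 4.05 ± 0.87 and Lcn2, an iron-sequestering protein of inflamed epithelia, by 3.92 ± 0.32. The 8 largest decreases, of which Scgb1b27, Smgc, Car6, Prol1 and Pip are on the list of acinar secretory products, were those of Scgb2b26 (-9.17 ± 0.56), Scgb1b27 (-7.94 ± 1.26), Wfdc12 (-7.46 ± 1.01), Smgc (-7.03 ± 1.91), Mucl2, Car6 (-6.94 ± 1.76), the proline-rich protein Prol1 (-6.38 ± 1.65) and the prolactin-induced protein Pip (-6.04 ± 1.25), with adjusted p between 1.6e-05 and 0.018. Irradiated Areg stood at 157, 38.4 and 23.2 CPM, and its log2 change was 2.88 without irradiated mouse 1 and 5.47 without untreated mouse 2. Of the decreased genes, Smgc is also on the fixed marker list of intercalated duct cells, and the intercalated duct-like share fell as well. The irradiated levels of 6 of the decreased genes came mostly from mouse 2, which held the acinar-like cells, with Smgc at 1.11, 237 and 0.871 CPM. Without it the changes were -10.53 (Scgb1b27), -10.37 (Wfdc12), -13.37 (Smgc), -8.48 (Mucl2), -12.41 (Car6) and -11.14 (Prol1), and without irradiated mouse 1 that of Pip was -7.25.

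Of 24 p53 targets 21 rose and 1 fell (23 adjusted over the list alone; camera adjusted p = 5.0e-18, adjusted p = 0.25 with an estimated correlation). The death receptors Fas (2.21 ± 0.12) and Eda2r (2.43 ± 0.14) and the p53 cofactor Trp53inp1 (1.65 ± 0.11) rose. Of 29 interferon response genes 27 rose and none fell (28 adjusted over the list alone; camera adjusted p = 6.2e-20, adjusted p = 0.25 with an estimated correlation). Irf7, a master regulator of the response (2.59 ± 0.18), Xaf1 (2.07 ± 0.17), the antiviral gene Ifit1 (2.04 ± 0.13) and Trim25 (1.91 ± 0.15) rose. Of 16 class I genes 15 rose (15 adjusted over the list alone; camera adjusted p = 5.5e-13, adjusted p = 0.25 with an estimated correlation). H2-Q7 (3.07 ± 0.15), H2-Q4 (2.40 ± 0.10) and H2-K1 (1.62 ± 0.09) rose. Senescence-associated secretory genes rose in 10 and fell in 3 of 15 cases (13 adjusted over the list alone; camera adjusted p = 6.5e-04, adjusted p = 0.25 with an estimated correlation). The protease inhibitor Timp1 (2.32 ± 0.18), the urokinase receptor Plaur (2.04 ± 0.22) and the adhesion gene Icam1 (1.75 ± 0.17) rose, and Igfbp5 (-1.35 ± 0.14) fell. With mice assigned by hashtag share Icam1 did not pass (0.97, adjusted p = 0.12). Of 18 NF-kB genes 10 rose and 2 fell (13 adjusted over the list alone; camera adjusted p = 9.0e-04, adjusted p = 0.25 with an estimated correlation). The subunits Relb (1.70 ± 0.19) and Nfkb2 (0.97 ± 0.11) and the inhibitor Nfkbia (1.22 ± 0.13) rose.

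Acinar products fell in 11 and rose in 1 of 15 cases (12 adjusted over the list alone; camera adjusted p = 2.8e-06, adjusted p = 0.25 with an estimated correlation). Scgb2b27 (-5.53 ± 0.38), the saliva peroxidase Lpo (-5.35 ± 0.48) and Oit1 (-4.42 ± 0.23) fell, with Lpo at -9.39 without irradiated mouse 2. Acinar regulators and fluid secretion genes fell in 15 and rose in 2 of 25 cases (17 adjusted over the list alone; camera adjusted p = 1.2e-08, adjusted p = 0.067 with an estimated correlation). Bhlha15 (Mist1), a transcription factor of secretory cells, fell by 4.08 ± 0.20, and the beta-adrenergic receptor Adrb1 (-2.78 ± 0.18) and the transcription factor Etv1 (-1.87 ± 0.12) fell as well. Without the acinar-like cells the log2 change of Etv1 was 0.28 (adjusted p = 0.47), and Oit1 no longer passed. Of 20 granular duct products 10 rose and 1 fell (12 adjusted over the list alone; camera adjusted p = 0.029, adjusted p = 0.69 with an estimated correlation). Klk1b5 (1.11 ± 0.22) and Klk1 (0.55 ± 0.07) rose and Esp18 (-4.89 ± 0.63) fell, beside the higher share of granular duct-like cells. Esp18 was at -6.02 without irradiated mouse 2. Immediate-early genes, which also respond to tissue dissociation, fell in 13 and rose in 1 of 18 cases (14 adjusted over the list alone; camera adjusted p = 5.4e-06, adjusted p = 0.35 with an estimated correlation). Klf2 (-3.82 ± 0.28), Fosb (-1.88 ± 0.16) and Zfp36 (-1.46 ± 0.14) fell and Myc (2.07 ± 0.16) rose. The mitochondrial share was 4.36% in the irradiated and 9.51% in the untreated cells.

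Heat shock genes fell in 5 of 13 cases (camera adjusted p = 0.037), Wnt genes in 3 of 12 (0.037), and Notch genes rose in 5 of 8 (0.037), unfolded protein genes in 9 of 22 (0.017) and class II genes in 3 of 6 (0.016), with adjusted p between 0.25 and 0.69 with an estimated correlation. Without irradiated mouse 1 the direction of the proliferation list turned (camera adjusted p = 0.99). None of 20 proliferation genes passed in edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 in DESeq2), with Mcm2 at -0.35 ± 0.17 and Tyms at -0.31 ± 0.16. In other settings 2 of them passed as lower, Tyms with thinned sums (-0.52, adjusted p = 0.040) and Hmgb2 with mice assigned by hashtag share (-0.41, 0.039) and with the stricter cell filter (-0.34, 0.041). Of 20 DNA repair genes 7 fell (4 adjusted over the list alone, camera adjusted p = 0.088, fry adjusted p = 0.011). Rpa1 (-0.70 ± 0.14) and Parp1 (-0.61 ± 0.17) fell, the latter not without untreated mouse 1 (-0.51, adjusted p = 0.075) or with the stricter cell filter (-0.50, 0.060). Duct ion transport genes (2 of 17 rose, 6 fell), basal keratins (7 of 19 rose), contractile genes (1 of 12 rose), luminal keratins and junctions (10 of 16 rose, 5 fell), and squamous genes (1 of 8 rose) did not pass camera as lists. The same held for progenitor-associated genes (4 of 15 rose, 6 fell), retinoic acid genes (2 of 9 rose, 2 fell), matrix genes (2 of 10 rose), oxidative stress genes (7 of 20 rose, 4 fell) and oxidative phosphorylation genes (4 of 23 rose, 2 fell). For the retinoic acid and the matrix genes the median and the camera test differed in sign.

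**Figure D3:**
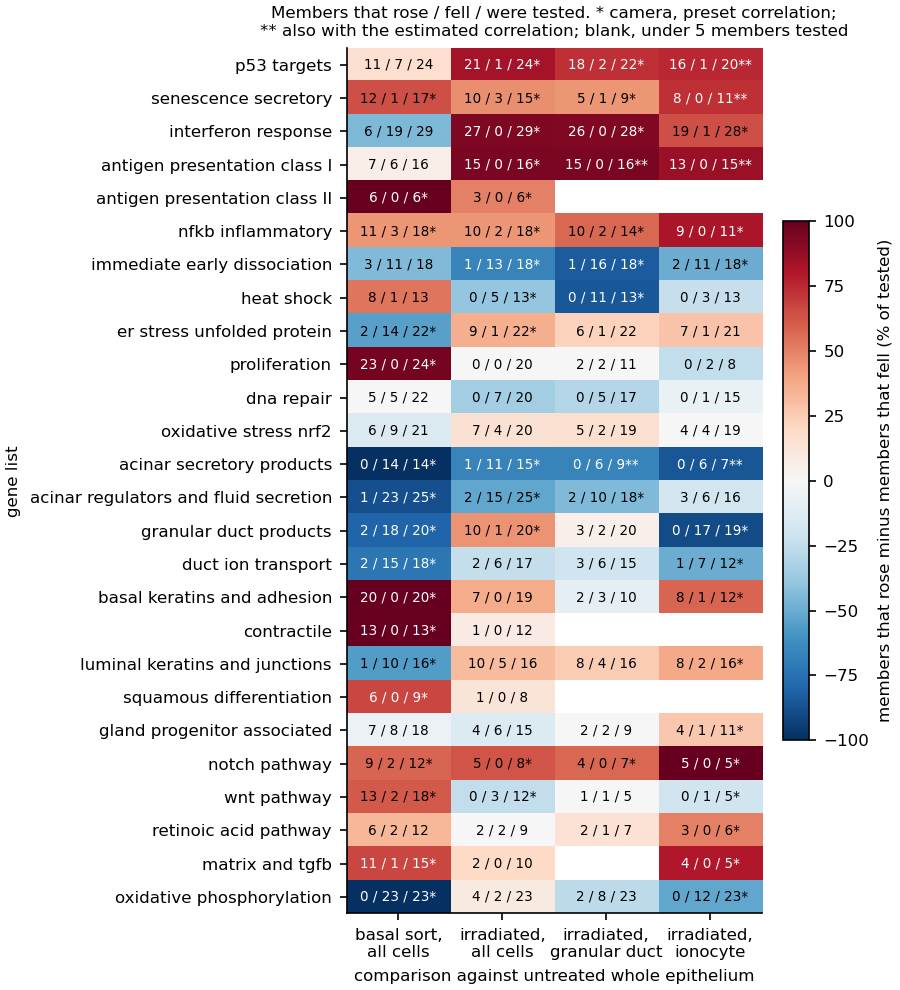
Gene lists (rows) in 4 comparisons against the untreated whole epithelium (columns): each cell gives the numbers of members that rose, fell and were tested, and its colour the members that rose minus those that fell (% of tested). Of 24 p53 targets 21 rose over all irradiated cells, 18 of 22 in granular duct-like cells and 16 of 20 in ionocyte-like cells.

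Within granular duct-like cells (cluster 11 in untreated mice, clusters 19 and 20 in irradiated mice), p53 targets, interferon genes and class I genes were higher after irradiation, and immediate-early and heat shock genes were lower. All 5 lists passed camera, and of these the class I genes alone passed with an estimated correlation (adjusted p = 0.022; 0.078 to 0.55 for the others). Bax rose from 36.5 ± 4.21 to 159 ± 16.5 CPM (log2 2.12 ± 0.12, adjusted p = 4.8e-07). Ifi27l2a, an interferon-induced protein, rose from 364 ± 130.1 to 2990.2 ± 516 CPM (3.04 ± 0.24, adjusted p = 3.6e-06), and B2m from 504 ± 30.5 to 1879 ± 107 CPM (1.90 ± 0.10, adjusted p = 2.9e-07). The heat shock gene Hspa1a fell from 730.1 ± 604 to 15.9 ± 5.93 CPM (-5.53 ± 0.61, adjusted p = 4.0e-05), with -4.68 without untreated mouse 3. Of 9829 genes tested, 1859 rose and 1879 fell. With upper-quartile factors 39.2% of the changed genes were higher in place of 49.7%. The median mitochondrial share of these cells was 10.1% ± 0.281 in untreated and 3.91% ± 0.328 in irradiated mice.

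Reg3g was at least 236-fold higher in the irradiated granular duct-like cells, or 153-fold without untreated mouse 2. The interleukin 1 receptor antagonist Il1rn rose by 5.57 ± 0.59, Areg by 5.32 ± 0.83, the interferon-inducible Ifi202b by 5.24 ± 0.73 and Morrbid by 4.59 ± 0.29. Smgc (-10.46 ± 1.09), Car6 (-6.85 ± 0.16), Prol1 (-6.22 ± 0.13) and Wfdc12 (-5.66 ± 0.31) were, with Hspa1a, the largest decreases. Irradiated Areg stood at 199.7, 48.3 and 33.4 CPM, and its change was 4.18 without irradiated mouse 1 and 5.92 without untreated mouse 2. Without untreated mouse 1 the changes were 6.29 (Il1rn), 5.21 (Morrbid) and -8.80 (Smgc), without untreated mouse 2 4.97 (Il1rn), without irradiated mouse 1 4.62 (Ifi202b) and without irradiated mouse 2 -5.06 (Wfdc12). Free RNA of the untreated library could give 48.9% of the untreated level of Smgc and at least 98.5% of that of Car6, Prol1 and Wfdc12 in these cells. Of 22 p53 targets 18 rose and 2 fell (20 adjusted over the list alone; camera adjusted p = 5.8e-13, adjusted p = 0.078 with an estimated correlation). Fas (2.20 ± 0.14) and Ccng1 (1.83 ± 0.13) rose and Btg2 (-2.38 ± 0.16) fell. Of 28 interferon genes 26 rose (26 adjusted over the list alone; camera adjusted p = 1.1e-23, adjusted p = 0.15 with an estimated correlation). Irf7 (2.65 ± 0.19), Xaf1 (2.38 ± 0.19) and Rtp4 (2.34 ± 0.16) rose. Of 16 class I genes 15 rose (15 adjusted over the list alone; camera adjusted p = 3.0e-19, adjusted p = 0.022 with an estimated correlation). H2-Q4 (2.82 ± 0.15) and H2-Q7 (2.67 ± 0.14) rose. Of 14 NF-kB genes 10 rose and 2 fell (12 adjusted over the list alone; camera adjusted p = 1.6e-04, adjusted p = 0.078 with an estimated correlation). Lcn2 (3.15 ± 0.34), Relb (2.14 ± 0.19), Birc3 (1.29 ± 0.16) and Csf1 (1.01 ± 0.13) rose.

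Immediate-early genes fell in 16 and rose in 1 of 18 cases (17 adjusted over the list alone; camera adjusted p = 7.2e-20, adjusted p = 0.12 with an estimated correlation). Klf2 (-4.60 ± 0.29), Fosb (-2.72 ± 0.14), Zfp36 (-2.57 ± 0.15) and Nr4a1 (-2.39 ± 0.16) fell. Heat shock genes fell in 11 of 13 cases (12 adjusted over the list alone; camera adjusted p = 1.6e-04, adjusted p = 0.55 with an estimated correlation). Hspa1b (-3.87 ± 0.57), Hsph1 (-2.54 ± 0.47) and Hspe1 (-1.07 ± 0.20) fell, with Hspa1b at -3.04 and Hsph1 at -1.60 without untreated mouse 3. Acinar products fell in 6 of 9 cases (6 adjusted over the list alone; camera adjusted p = 7.2e-20, adjusted p = 0.014 with an estimated correlation). For 5 of the 6, all but Smgc, free RNA could give at least 50% of the untreated level. Of 20 granular duct products 3 rose, 2 fell and 15 did not pass (4 adjusted over the list alone; camera adjusted p = 0.72). The aspartic protease Ren1 (1.56 ± 0.48), Klk1b16 (1.51 ± 0.39) and Crisp3 (0.91 ± 0.29) rose and Esp18 (-4.29 ± 0.69) fell. The calls of Ren1, Klk1b16 and Crisp3 ended in DESeq2, with the stricter cell filter and without untreated mouse 1, those of Ren1 and Crisp3 without untreated mouse 3, and that of Crisp3 without irradiated mouse 3. In DESeq2 the changes were 1.62, 1.53 and 0.94, and with the stricter filter 0.46, 0.36 and 0.0082. Ren1 and Crisp3 also did not pass with the default hashtag start. Their log2 changes without irradiated mouse 3 were 0.95 and 0.46. That of Esp18 was -7.99 without irradiated mouse 2 and -3.54 without untreated mouse 2. The direction of the list turned without untreated mouse 1 or irradiated mouse 3 (camera adjusted p = 0.97 and 0.40). Unfolded protein genes rose in 6 and fell in 1 of 22 cases (7 adjusted over the list alone; camera adjusted p = 0.076). Chac1 (3.39 ± 0.37) and Trib3 (3.24 ± 0.32), targets of the integrated stress response, (3.98 without untreated mouse 1) rose with Asns (0.74 ± 0.12) and Xbp1 (0.71 ± 0.10). Acinar regulators (2 of 18 rose, 10 fell), senescence-associated genes (5 of 9 rose, 1 fell) and Notch genes (4 of 7 rose) passed camera with adjusted p of 3.4e-04, 0.021 and 0.021, and had adjusted p of 0.078, 0.15 and 0.34 with an estimated correlation. The other 10 lists tested here did not pass camera.

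Within ionocyte-like cells (cluster 13 in untreated mice, cluster 15 in irradiated mice), p53 targets, class I genes, senescence-associated and NF-kB genes and luminal keratins were higher after irradiation, and granular duct products and ion transport genes were lower. All 7 lists passed camera, and the p53 targets, class I genes and senescence-associated genes also passed with an estimated correlation (adjusted p = 0.042, 0.042 and 0.038; 0.068 to 0.20 for the others). Cdkn1a (p21), the cell cycle inhibitor, rose from 17.1 ± 5.43 to 228 ± 88.4 CPM (log2 3.67 ± 0.27, adjusted p = 5.7e-07). H2-K1 rose from 1369 ± 107 to 4639 ± 133 CPM (1.76 ± 0.07, adjusted p = 2.4e-09), and Cxcl2, a neutrophil chemokine, from 0.948 ± 0.910 to 68.1 ± 6.07 CPM (6.27 ± 0.32, adjusted p = 2.2e-08), with 5.58 and 7.07 without untreated mice 1 and 3. Of 8896 genes tested, 1337 rose and 940 fell. With upper-quartile factors, which shifted the median by -0.109 on the log2 scale, 40.8% of the changed genes were higher in place of 58.7%. The number of changed genes was 1450 in DESeq2, 1493 with sums thinned to the smallest mouse, 1170 with a stricter cell filter and 1505 without irradiated mouse 2. The median mitochondrial share of these cells was 12.1% ± 0.204 in untreated and 5.79% ± 0.358 in irradiated mice.

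Calcb was at least 450.1-fold higher in irradiated ionocyte-like cells, the mesothelin gene Msln at least 44.0-fold and the trypsin-family gene Try5 at least 43.3-fold (0 counts of each in untreated mice). Irradiated Msln stood at 95.2, 16.8 and 8.30 CPM, and its limit was 28.7-fold without irradiated mouse 1. Without untreated mouse 1 the limits were 273-fold (Calcb), 26.7-fold (Msln) and 26.3-fold (Try5). Plac8, with 1 untreated count, was higher by a ratio of 227 (95% counting interval 40.5 to 8988), 138 without untreated mouse 1 and at least 54.6 without untreated mouse 3, and Sult1c1 rose by 6.71 ± 0.19. The largest decreases, all but Scgb2b26 on the list of acinar secretory products, were those of Smgc (-7.97 ± 0.72), Prol1 (-7.67 ± 0.54), Scgb2b26 (-7.64 ± 0.40), Scgb1b27 (-7.41 ± 0.38) and Pip (-7.32 ± 0.35), of which free RNA could give between 60.7% and 131% of the untreated level. Smgc was at -6.97 without untreated mouse 1 and -7.17 without irradiated mouse 2, and Prol1 at -6.88 without untreated mouse 3. Acinar products as a list fell in 6 of 7 cases (6 adjusted over the list alone; camera adjusted p = 1.6e-32, adjusted p = 0.038 with an estimated correlation). Free RNA could give at least 50% of the untreated level of all 6. Of 20 p53 targets 16 rose and 1 fell (17 adjusted over the list alone; camera adjusted p = 3.7e-15, adjusted p = 0.042 with an estimated correlation). The kinase Plk2 (1.91 ± 0.14), Trp53inp1 (1.74 ± 0.14) and Bax (1.16 ± 0.09) rose. Of 15 class I genes 13 rose (14 adjusted over the list alone; camera adjusted p = 8.5e-31, adjusted p = 0.042 with an estimated correlation). H2-Q7 (3.98 ± 0.16), H2-Q4 (2.12 ± 0.10) and H2-D1 (1.79 ± 0.07) rose. Of 11 senescence-associated genes 8 rose (8 adjusted over the list alone; camera adjusted p = 8.1e-10, adjusted p = 0.038 with an estimated correlation). Plaur (3.29 ± 0.34), Icam1 (2.63 ± 0.22) and Timp1 (2.13 ± 0.28) rose, with Timp1 at 2.75 without untreated mouse 1. Interferon genes rose in 19 and fell in 1 of 28 cases (22 adjusted over the list alone; camera adjusted p = 7.0e-07, adjusted p = 0.35 with an estimated correlation). Oas1a (3.87 ± 0.36), Irf7 (2.36 ± 0.18) and Bst2 (2.00 ± 0.22) rose, and Ifi27 (-1.26 ± 0.09) fell.

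Of 11 NF-kB genes 9 rose (9 adjusted over the list alone; camera adjusted p = 2.4e-09, adjusted p = 0.068 with an estimated correlation). Nfkbia (1.85 ± 0.14), Csf1 (1.79 ± 0.14), Relb (1.48 ± 0.19) and Cxcl16 (0.93 ± 0.10) rose. Luminal keratins and junction genes rose in 8 and fell in 2 of 16 cases (12 adjusted over the list alone; camera adjusted p = 4.5e-05, adjusted p = 0.068 with an estimated correlation). Cldn4 (1.71 ± 0.12), Krt8 (1.70 ± 0.08) and Krt18 (1.01 ± 0.08) rose. All 5 Notch genes tested rose (5 adjusted over the list alone; camera adjusted p = 1.5e-04, adjusted p = 0.13 with an estimated correlation). Jag1 (2.24 ± 0.43), Notch3 (1.77 ± 0.23), Hes1 (1.03 ± 0.10) and Rbpj (0.74 ± 0.13) rose. Jag1 was at 2.86 without untreated mouse 2, and Rbpj did not pass with the stricter cell filter (0.43, adjusted p = 0.15). Granular duct products fell in 17 of 19 cases (17 adjusted over the list alone; camera adjusted p = 5.3e-20, adjusted p = 0.068 with an estimated correlation). Klk1b27 (-3.26 ± 0.17), Klk1b9 (-2.17 ± 0.17), Klk1b11 (-1.95 ± 0.18) and Klk1b26 (-1.73 ± 0.16) fell. Free RNA could give between 3.24% and 23.2% of the untreated level of these 4 genes, and the call of Klk1b11 was lost when only hashtag doublets were removed (-1.01, adjusted p = 0.067). Duct ion transport genes fell in 7 and rose in 1 of 12 cases (9 adjusted over the list alone; camera adjusted p = 0.0034, adjusted p = 0.20 with an estimated correlation). The carbonic anhydrase Car2 (-1.93 ± 0.40), the sodium channel subunits Scnn1g (-1.26 ± 0.26) and Scnn1b (-0.98 ± 0.13), and Fxyd2 (-0.61 ± 0.09) fell. Car2 did not pass when only hashtag doublets were removed (-0.49, adjusted p = 0.39). Oxidative phosphorylation genes fell in 12 of 23 cases (15 adjusted over the list alone; camera adjusted p = 0.0019, adjusted p = 0.49 with an estimated correlation). Atp5g1 (-0.56 ± 0.08), Atp5b (-0.52 ± 0.07), Atp5a1 (-0.40 ± 0.07) and Cox4i1 (-0.39 ± 0.06) fell, beside the mitochondrial shares of 12.1% and 5.79%. Immediate-early genes fell in 11 and rose in 2 of 18 cases (14 adjusted over the list alone; camera adjusted p = 0.0018, adjusted p = 0.41 with an estimated correlation). Klf2 (-2.38 ± 0.32), Fos (-1.37 ± 0.21) and Zfp36 (-1.29 ± 0.17) fell and Ier3 (0.51 ± 0.08) rose. Basal keratins (8 of 12 rose, 1 fell), matrix genes (4 of 5 rose), progenitor-associated genes (4 of 11 rose, 1 fell), retinoic acid genes (3 of 6 rose) and Wnt genes (1 of 5 fell) passed camera with adjusted p between 0.0018 and 0.045, and had adjusted p between 0.13 and 0.24 with an estimated correlation. The other 6 lists tested here did not pass camera.

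**Figure D4:**
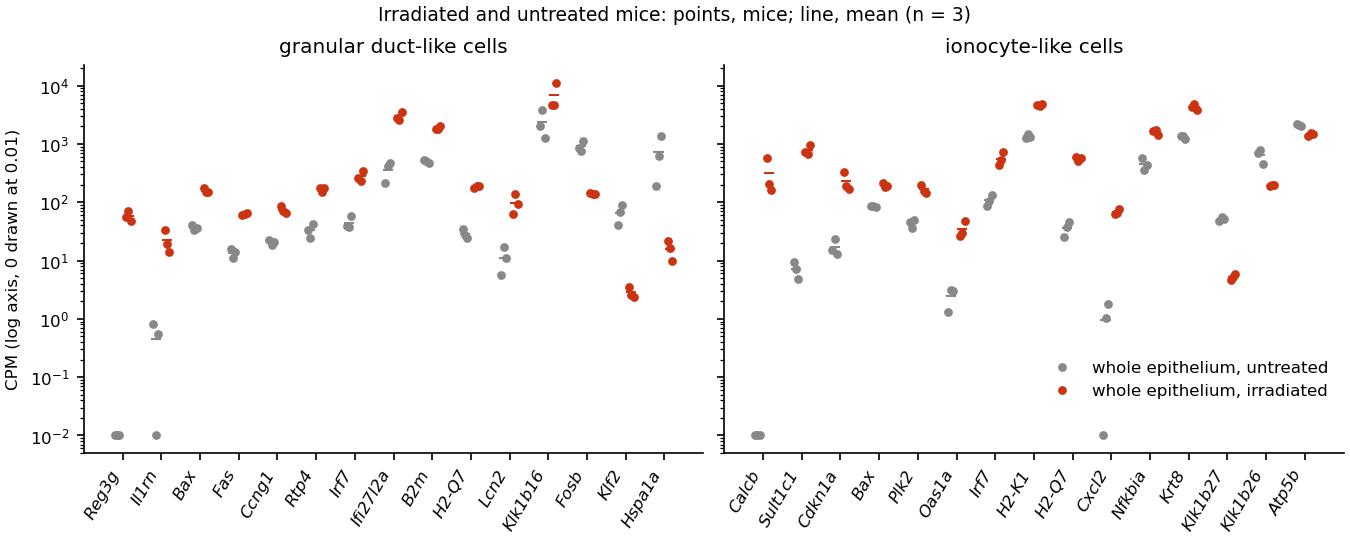
CPM (log axis, values of 0 drawn at 0.01) of 15 named genes in granular duct-like cells and 15 in ionocyte-like cells of each untreated and irradiated mouse; points are mice and lines are means (n = 3 mice). Bax stood at 36.5 and 159 CPM in granular duct-like cells and at 86.0 and 194 CPM in ionocyte-like cells.

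Whether the irradiation effect differed between granular duct-like and ionocyte-like cells was tested with an interaction term and the mouse as a block. The difference passed for 1275 of 10497 genes, with 663 log2 changes higher and 612 lower in granular duct-like cells. Higher and lower refer here to the signed log2 change, so a deeper fall counts as lower. Interferon genes had the higher change in granular duct-like cells in 13 of 29 cases and in ionocyte-like cells in none, with Rtp4 (difference of log2 changes 2.00 ± 0.17 SE), Ifi27l2a (1.65 ± 0.12) and Ifi27 (1.44 ± 0.13). Immediate-early genes had the higher change in ionocyte-like cells in 16 of 18 cases and in granular duct-like cells in 1, with Nr4a1 (-2.75 ± 0.15), Fos (-1.83 ± 0.15) and Fosb (-1.59 ± 0.14). Heat shock genes did so in 9 of 13 cases, with Hspa1a (-3.39 ± 0.24) and Hspb1 (-2.35 ± 0.23). Granular duct products had the higher change in granular duct-like cells in 17 of 20 cases, with Klk1b24 (3.59 ± 0.34) and Klk1b27 (3.21 ± 0.22). Among 23 p53 targets the change was higher in granular duct-like cells for 6, with Mdm2, the p53 ubiquitin ligase (1.70 ± 0.24), and Bax (0.96 ± 0.14), and lower for Btg2 (-1.79 ± 0.11). Class I genes differed in 3 of 16 cases, with H2-Q7 (-1.30 ± 0.22) among them, NF-kB genes in 4 of 16, with Nfkbia (-1.10 ± 0.13), and oxidative phosphorylation genes in 3 of 23. With sums thinned to the smallest total 541 genes passed, with the stricter cell filter 795 (512 higher and 283 lower in granular duct-like cells), without untreated mouse 3 832 and without irradiated mouse 2 846.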

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

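The splits of the mice in this part were planned. The tests that weigh explanations here were chosen after the results were seen, and the lists, the markers and the 5 fits compared here were fixed before the data were examined, unlike the 5 starting clusters of the hashtag calls and the alternatives named as added.

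The irradiation effect differed between granular duct-like and ionocyte-like cells, by a test of the difference itself, for 1275 of 10497 genes. Of these, 67 changed in opposite directions in the classes, and 27 of the 67 were higher in granular duct-like cells. The largest opposite differences (log2 change in granular duct-like minus that in ionocyte-like cells) were those of Edn2 (-7.56), Dcn (-5.31), Sema4c (-3.74), Ccn1 (-3.30), St3gal1 (-3.22), Thbs1 (-3.05), Wfdc18 (-3.00) and Car2 (2.80), named here after their values were seen. For p53 targets the differences were -1.79 for Btg2, 1.70 for Mdm2, 0.96 for Bax and 3.71 for Ddit4l. For interferon genes they were 1.65 for Ifi27l2a, 2.00 for Rtp4, 1.44 for Ifi27 and 1.15 for Xaf1, and for class I genes -1.30 for H2-Q7, 0.72 for H2-Q4 and 0.51 for Tapbp. For NF-kB genes they were -1.10 for Nfkbia, 0.64 for Relb, -0.78 for Csf1 and -3.16 for Tnf. Immediate-early genes differed by -2.75 (Nr4a1), -1.83 (Fos), -1.59 (Fosb) and -1.35 (Jun), and heat shock genes by -3.39 (Hspa1a), -2.81 (Hspa1b), -2.35 (Hspb1) and -1.09 (Dnajb1). Granular duct products differed by 3.21 (Klk1b27), 1.91 (Klk1b11), 3.59 (Klk1b24) and 1.86 (Klk1b5), and oxidative phosphorylation genes by 0.36 (Cox6c), 0.34 (Cox7a2) and 0.39 (Ndufa1). The difference of Csf1 was 0.15 with the stricter cell filter (adjusted p = 0.85). That of Tnf, which was tested in neither class alone, had an adjusted p of 0.049 and did not pass with any mouse left out. Those of Ddit4l, H2-Q4, Tapbp, Relb, Klk1b11 and the oxidative phosphorylation genes did not pass in at least 1 setting. No single explanation was tested for these differences, apart from that of the granular duct products below.

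Acinar RNA also appeared in barcodes that the comparisons leave out. Of 1719 untreated barcodes without a hashtag call, 48.5% were rich in acinar RNA (95% exact binomial interval 46.1% to 50.9%), against 7.99% of the 2216 barcodes with 1 hashtag and 0.340% of the 294 irradiated barcodes without a call. The acinar share of the untreated kept cells is therefore a low estimate of that among all barcodes.

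Acinar-like cells and acinar RNA were lower in the irradiated library. That the cell filter and the hashtag calls removed acinar cells that still made acinar products is argued against by all deposited barcodes. Of these, 0.572% were rich in acinar RNA in the irradiated and 18.0% in the untreated library. That acinar cells still making these products broke after the sort and left free RNA is argued against by the products themselves. With Mucl2 they gave 0.0149% of the UMIs of irradiated ionocyte-like cells and 1.78% of those of untreated ones. Both tests recognise acinar cells by these products, so they cannot decide for acinar cells that no longer made them. It stays open that acinar cells changed their products and fell into another cluster, since clustering each library alone named 5.53% of irradiated and 5.71% of untreated cells acinar-like (114 and 122 cells), and 83 of the 114 lay in the joint cluster 12, which was named intercalated duct-like. Loss of acinar RNA after irradiation, a difference in age at collection and losses before or during the sort stay open as well, with no test here.

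The p53 targets, interferon genes and class I genes were higher in irradiated cells of both classes, though with an estimated correlation only the class I list passed in both (interferon genes in neither, p53 targets in ionocyte-like cells). Free RNA of the irradiated library is argued against under the assumed ratios, since it could give at least 50% of the irradiated level of 0 of the 107 members that rose. Immune cells captured with the epithelial cells are argued against by the median immune marker at 0.169 CPM in irradiated granular duct-like cells and by the sort, which left out Cd45-positive cells, with the exception of Lyz2 at 20.7 CPM in irradiated ionocyte-like cells. Irradiation and library preparation or age in place of irradiation cannot be told apart, with 1 library per group.

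Granular duct products were lower in irradiated ionocyte-like cells, though as a list not with an estimated correlation (adjusted p = 0.068). In untreated ionocyte-like cells these products stood at 24.1% of their library level and acinar products at 3.07%. That would argue against free RNA from granular duct cells as the whole cause if free RNA held the ratios of its library. Those ratios were not measured, so this cause stays open. Acinar products with Mucl2 took 50.1% of the UMIs of all untreated barcodes and 8.35% of those outside the cell filter. The median ionocyte-like cell held 0.894% of its UMIs from granular duct products in untreated and 0.332% in irradiated mice. Doublets with granular duct cells are argued against as the whole cause, since the 5% of untreated cells with the most such UMIs held 21.3% of them (31.5% in irradiated cells), and not most of them. A loss of these transcripts after irradiation stays open and is a hypothesis found and tested on the same data. Library preparation or age in place of irradiation cannot be told apart from it, with 1 library per group.

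Splitting the 6 mice of each comparison in all 10 ways gave as many genes as the real split in 1 of 10 splits, the real one, for each of the 5 fits. The real counts were 9469 (basal sort), 4876 (all irradiated cells), 3738 (granular duct-like), 2277 (ionocyte-like) and 1275 (difference between the classes), and the highest other split gave 0 genes in each. With 10 splits the share cannot fall under 0.05.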

How the results depend on the processing

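Tests added after seeing the data are the default hashtag start, barcodes without a hashtag call kept, free RNA genes or acinar-like cells left out, the low-UMI cluster 10 counted as ionocyte-like, and most settings of the class difference; the others were planned.

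The number of changed genes ranged over the settings from 7750 to 10423 for the basal sort, 3208 to 5210 for all irradiated cells, 2787 to 4290 for granular duct-like cells, 1170 to 2639 for ionocyte-like cells and 541 to 1488 for the difference between the classes. Counts that moved by more than 1.5 times were 3208 with the hashtag share rule (all irradiated cells), 1450 with DESeq2, 1493 with thinned sums and 1170 with the stricter cell filter (ionocyte-like), and 541 with thinned sums and 795 with the stricter filter (difference between the classes). Thinned sums and fewer cells hold fewer counts; for DESeq2 and the share rule the cause was not tested. Leaving out each mouse gave 1505 to 2089 genes for ionocyte-like cells (1505 without irradiated replicate 2), 832 to 1198 for the difference (832 without untreated replicate 3, 846 without irradiated replicate 2) and 3558 to 4695 for all irradiated cells. These fits leave a group with 2 mice. With the replicate number as a block the counts were 9221, 3964, 3605 and 2105, and 11 and 6 classes differed. The numbers do not pair the mice, since their deviations correlated between -0.194 and 0.0492.

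With an estimated correlation, lists called by camera fell from 17 to 0 (basal sort), 14 to 0 (all irradiated cells), 10 to 2 (granular duct-like) and 17 to 4 (ionocyte-like). The number of cell classes that differed ranged from 9 to 11 (basal sort) and 4 to 9 (irradiated).

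Directions turned for 20 values of class shares, 14 of them where neither value passed. The luminal duct-like share of the basal sort was at log2 0.031 with TMM factors over classes. That of the irradiated epithelium was at 2.62 with the hashtag share rule, 3.24 at resolution 2 and 2.73 with each library clustered alone, all past the threshold, and at 0.015 with TMM factors, 0.20 with the default hashtag start and -1.17 to 0.0058 with each mouse left out, none past it. The unnamed share was at -2.18 with each library clustered alone and at -6.00 with cluster 10 counted as ionocyte-like, since its cells moved to another class, both past the threshold, and at -0.051 with the block, -0.23 at resolution 2 and -0.34 to 0.56 with each mouse left out. The cycling share, never past it, was at -1.06 with the share rule, -0.24 with the stricter filter, -0.027 at resolution 2, -0.47 with the default start and -0.55 to 0.51 with each mouse left out. Lists turned for proliferation (all irradiated cells; adjusted p 0.13 to 0.99 with each mouse left out) and granular duct products (granular duct-like cells; 0.21 to 0.97). Of the named genes Etv1 was at 0.28 without acinar-like cells, where the missing cells are the cause, and Csf1 at 0.15 (difference between the classes) with the stricter filter. The cause of the other turns was not tested. Of the other values for named genes, 3934 kept direction and call, 82 lost the call and 3 gained it; for class shares it was 295, 21 and 16, and for lists 284, 38 and 3.

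With barcodes without a hashtag call kept, the acinar-like percentage went from 5.52 to 19.1 (untreated) and from 0.388 to 0.384 (irradiated). Untreated luminal duct-like cells went from 1.73% to 11.4%, intercalated from 25.0% to 11.1%, granular from 29.5% to 17.4% and unnamed from 6.04% to 16.5%. Irradiated intercalated duct-like cells went from 5.33% to 0.384% and granular from 54.8% to 50.4%. The share rule could not be run for granular duct-like and ionocyte-like cells or their difference, since a mouse held fewer than 20 cells.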

Other observations

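The tests in this part were chosen after the values were seen, as were the genes.

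Cluster 12 was named intercalated duct-like, and that name is in doubt for its irradiated cells, since 83 of the 101 were named acinar-like with each library clustered alone. It held 63, 38 and 67 cells of the untreated mice and 19, 68 and 14 cells of the irradiated mice. In these cells the saliva protein gene Bpifa2 stood at 16150, 9141 and 7.17 CPM in irradiated mice 1, 2 and 3 and at a mean of 0.493 CPM in untreated mice, and Dcpp3 at 11021, 5234 and 86.1 CPM against a mean of 6.33 CPM. Csn3, with 0 untreated counts, was at least 460-fold higher over the group but at 3507, 18.4 and 857 CPM in irradiated mice 1, 2 and 3 (at least 95.5-fold without mouse 1 and 1364-fold without mouse 2). The basal keratin Krt17 was at least 333-fold higher, or 538-fold without mouse 2. Lif stood at 132, 353 and 115 CPM in irradiated mice against a mean of 8.27 CPM in untreated mice, Cxcl2 at 781, 2247 and 897 against 169 CPM, and Apoe at 933, 75.0 and 262 against 5.68 CPM. Without irradiated mouse 2 the means of Lif and Cxcl2 were 124 and 839 CPM, and without mouse 1 that of Apoe was 168 CPM. Aqp5 stood at 297, 17.6 and 7.17 CPM in irradiated mice against a mean of 4.30 CPM, and Pip at 5383, 171 and 3.59 CPM against a mean of 452 CPM. Lower in irradiated mice were Esp4 (191 and 930 CPM), Kit (41.9 and 109 CPM) and Mucl2 (228 and 17350 CPM), though free RNA could give 68.9% of the untreated level of Mucl2 (0.221% for Esp4 and 0.421% for Kit). Wfdc18 stood at 22577 and 31437 CPM. The exact two-sided permutation p was 0.4 for Wfdc18, 1 for Pip and 0.1 for each of the other genes, the smallest that 3 mice against 3 can give.

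The basal sort held 115 endothelial-like cells, although Cd31-positive cells had been excluded. They carried Pecam1 (Cd31) at 1598 ± 230.1 CPM and Cdh5 at 710 ± 46.6 CPM (mean ± SD, n = 3 mice), Itga6 (Cd49f) at 213 ± 79.8 CPM and Epcam at 13.3 ± 11.9 CPM, with a median of 3276 UMIs per cell. In basal duct-like cells of the same mice Pecam1 stood at 2.05 ± 1.34, Itga6 at 173 ± 14.3 and Epcam at 1644 ± 108 CPM, with a median of 14033.5 UMIs.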
